A study of Ailuropoda melanoleuca with 25 samples.

How the data were processed

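RNA was extracted with a column kit and made into sequencing libraries from 2 μg of total RNA with an NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name kallisto, a pseudoaligner that assigns reads to transcripts without full alignment. Its version, index and genome build are not given in the sources used here. Each library has 1 deposited table with, for each of 22924 gene models, a length, an effective length, an estimated count and a TPM value, per the file headers. The deposited estimated counts need not be whole and were rounded to whole numbers for the tests. The deposited TPM values are scaled to effective length and to the library total by the authors' tool, and were used only for alternatives. The list of models was identical in all 25 tables. Of the model lengths 91.6% are multiples of 3, so they are called coding lengths here. Models lie on 21 scaffolds named HIC_ASM and 149 named ORI.

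The files do not pair model identifiers with gene names, and 0 of them occurred in the RefSeq table at hand (assembly ASM200744v3). The 362 gene symbols of the lists fixed before the data were examined therefore matched no model, and no named pathway or cell type marker was tested. In their place, lists were drawn from the comparisons after the data were examined (models called and over 2-fold changed), and each was tested only in comparisons that share no library with it. Reads shared between near-identical models cannot be told apart in these tables, so single models are examples.

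Groups and replicate numbers come from sample titles. All 25 libraries entered 1 fit of 12 groups with 13 residual degrees of freedom, because most groups hold 2 libraries. Models were kept by filterByExpr on the groups (17225 models), library sizes were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 gave quasi-likelihood F tests with robust dispersion, adjusted by Benjamini-Hochberg over all models tested. A model was called at an adjusted p under 0.05. Fold changes are edgeR log2 fold changes with an SE from the F statistic, and CPM values are TMM-scaled. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and 24 list tests were adjusted together. With the preset correlation all but 3 of the 24 passed and with the estimated one all but 7, and the printed values are those with an estimated correlation. Libraries were placed between PF and GPiPSC by the mean log2 CPM (prior count 2) over a list. The number of models shared by independent lists is the product of the list sizes divided by the models tested.

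The rule for named models was fixed before the data were examined. It takes, among genes with a symbol, the 5 called ones per direction with the largest fold changes that have at least 10 counts summed over the lower side, a mean of at least 10 CPM on the higher side and no overlap between the libraries of the sides. For the difference between LB and XR it asks only for a mean of at least 10 CPM in 1 of the groups. Without symbols the rule could not be applied as fixed, and its parts on named pluripotency genes and list members name nothing here. It was applied to all models, and the 2 per direction and comparison with the largest changes are printed, a change made after the data were examined. No fold is printed for a model with 3 counts or fewer in a library of the groups compared. The alternatives were RLE size factors, DESeq2 1.42.0, no filter, only the libraries compared, a replicate block, effective-length offsets, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), glmTreat against 2-fold, PF or GPiPSC of LB or XR alone where both form the reference, and each library left out in turn. Where that leaves a group with 1 library, it is assumed to vary like the other groups. A covariate for the deviation shared by several libraries, list medians and positions on the TPM scale, list tests without LB GPiPSC replicate 3, 10 simulations of unchanged LB and XR groups and 1000 draws of models at matched levels (20 bins of mean log2 CPM) for the BACL lists were added after the data were examined. RLE moved the median log2 fold change of all models by less than 0.1 in each comparison.

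The edgeR step was tested on simulated counts of 17225 models, with 50 models changed at each fold. In the A83-01 comparison it recovered 12% of 2-fold, 70% of 4-fold and 96% of 8-fold changes with 1 false call, and in the LB comparison 10%, 86% and 92% with 5 false calls. None of the simulated 1.5-fold changes were recovered in either. Apart from the changed models, these counts were drawn with 1 mean level and 1 spread per model for all groups. In the data the spread between replicates differed, with a chi-square per degree of freedom of 2.32 in control day 16, 29.4 in A83-01 day 16 and 118 in LB PF. The rates of recovery and false calls therefore do not show those of the real comparisons. Totals of 8627980 to 14890300 counts put a floor of 3 counts at 0.176 to 0.376 TMM-scaled CPM, depending on the library, which covers counting error only. Steps of expression along scaffolds were sought on models with a mean log2 CPM above 4, with at least 40 models on each side, the number in the identifier taken as the order.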

Results

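Messenger RNA was sequenced in 25 libraries of giant panda (Ailuropoda melanoleuca) cells from a study of reprogramming, in which primary fibroblasts (PF) were turned into induced pluripotent stem cells (GPiPSC) with non-integrating episomal vectors. The labels name 12 groups. LB PF, XR PF, XR GPiPSC, stage I day 8, stage I day 24, stage II day 8, control day 16, A83-01 day 16, BACL LB GPiPSC, BACL control and BACL-CHIR99021 had 2 libraries each, and LB GPiPSC had 3. The labels do not say what LB, XR and BACL stand for, and they give no LB or XR for the stage, day 16, BACL control and BACL-CHIR99021 libraries. Total estimated counts ran from 8627980 in LB PF replicate 2 to 14890300 in XR PF replicate 2. The files list 22924 gene models by an assembly identifier and do not pair these with gene names, so changes are described for groups of gene models, with a few identifiers as examples. Of these models, 17225 had enough counts to be tested. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates correlated between 0.944 (LB PF) and 0.995 (BACL LB GPiPSC) in log2 CPM across models. The BACL replicate pairs lay closest to sampling noise, with a chi-square per degree of freedom of 1.20 to 1.61, against 2.32 to 119 in the other groups, and every pair differed by more than sampling noise. The tests pool the spread over the 12 groups, so p-values can be too small for groups that vary more and too large for those that vary less.

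**Figure D1:**
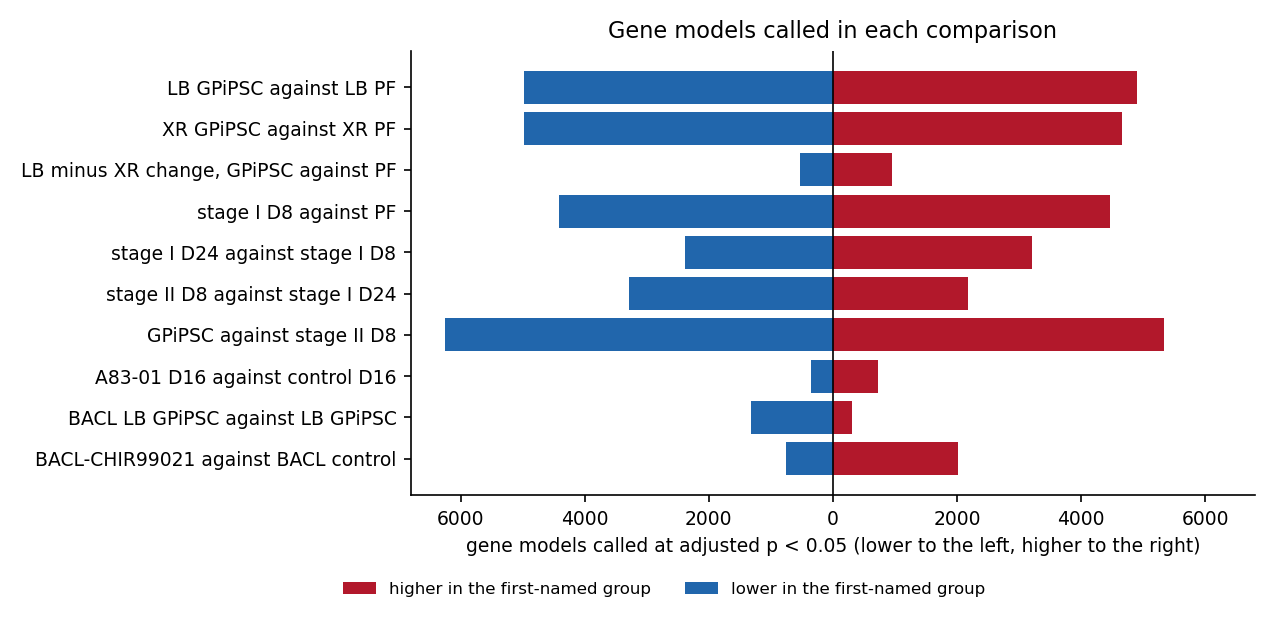
Number of gene models called in each of 10 comparisons (horizontal axis), with models higher in the first-named group to the right of 0 and models lower in it to the left. GPiPSC against stage II day 8 has 11600 calls and A83-01 against its control 1072.

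To see how reprogrammed cells differed from the fibroblasts of the same label, LB GPiPSC were compared with LB PF. In LB GPiPSC 4908 gene models were higher and 4974 lower, and 1716 and 1725 of these differed over 8-fold. The model evm.model.HIC_ASM_8.1452 rose from 1.20 ± 0.502 CPM (SD, n = 2) to 339 ± 35.7 CPM (SD, n = 3), a log2 fold change of 8.08 ± 0.51 (SE), and evm.model.HIC_ASM_11.877 rose from 0.490 ± 0.350 to 142.5 ± 40.0084 CPM. The model evm.model.HIC_ASM_13.784 fell from 13295 ± 10531 CPM in LB PF to 0.493 ± 0.420 CPM, and evm.model.HIC_ASM_1.498 from 3362 ± 452 to 0.407 ± 0.231 CPM. The adjusted p of edgeR's quasi-likelihood test for these 4 models was 1.99e-10, 9.44e-08, 4.1e-12 and 9.92e-15. Limma-trend on log2(TPM + 1) differs in test, unit, pseudocount and scaling. It gave 61.7% of calls higher against 49.7%, and a median over all models of 0.21 against 0.00. RLE, which like TMM corrects for library composition where TPM does not, gave 51.0%. Mean TMM factors were 1.32 in LB GPiPSC and 0.975 in LB PF. Without LB GPiPSC replicate 3, which stood apart from its group, 9379 models were called.

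XR GPiPSC were compared with XR PF in the same way, and changed in many of the same models. In XR GPiPSC 4657 models were higher and 4977 lower. The model evm.model.HIC_ASM_8.1452 rose again, from 1.000 ± 0.758 to 316 ± 21.7 CPM (SD, n = 2 each; log2 fold change 8.26 ± 0.52 SE, and 9.38 without XR PF replicate 1), and evm.model.HIC_ASM_13.733 rose from 0.493 ± 0.354 to 167 ± 23.2 CPM. The models evm.model.HIC_ASM_4.1592 and evm.model.HIC_ASM_1.498 fell from 3910 ± 1121 to 0.409 ± 0.0581 CPM and from 5570 ± 171 to 0.633 ± 0.288 CPM, with log2 fold changes of -13.19 ± 0.55 and -13.09 ± 0.45 (SE). Their adjusted p-values from edgeR were 3.72e-10, 1.64e-08, 7.00e-12 and 2.38e-13. Called higher in both LB and XR were 3418 models and lower in both 3652, where independent lists of these sizes would share 1327 and 1437. Higher in LB and lower in XR were 70, and 44 the reverse. The LB and XR comparisons share no library, but LB GPiPSC replicate 3, which lay nearer XR GPiPSC than its own group, is included. The overlaps and the correlations below were not computed without it. Across models, which are not independent replicates, the fold changes correlated at 0.85 (Pearson) and 0.80 (Spearman). Of the 4091 models over 2-fold higher in LB GPiPSC, 3056 rose and 45 fell in XR GPiPSC, with a median log2 fold change of 2.08 against -0.45 in the other models (adjusted p = 6.18e-05 with an estimated correlation, camera). Of the 4238 over 2-fold lower in LB GPiPSC, 3247 fell and 31 rose, with a median of -2.32 against 0.47 (adjusted p = 8.89e-10). With limma-trend on log2(TPM + 1), 62.3% of calls were higher against 48.3%, and the median over all models was 0.28 against 0.00.

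**Figure D2:**
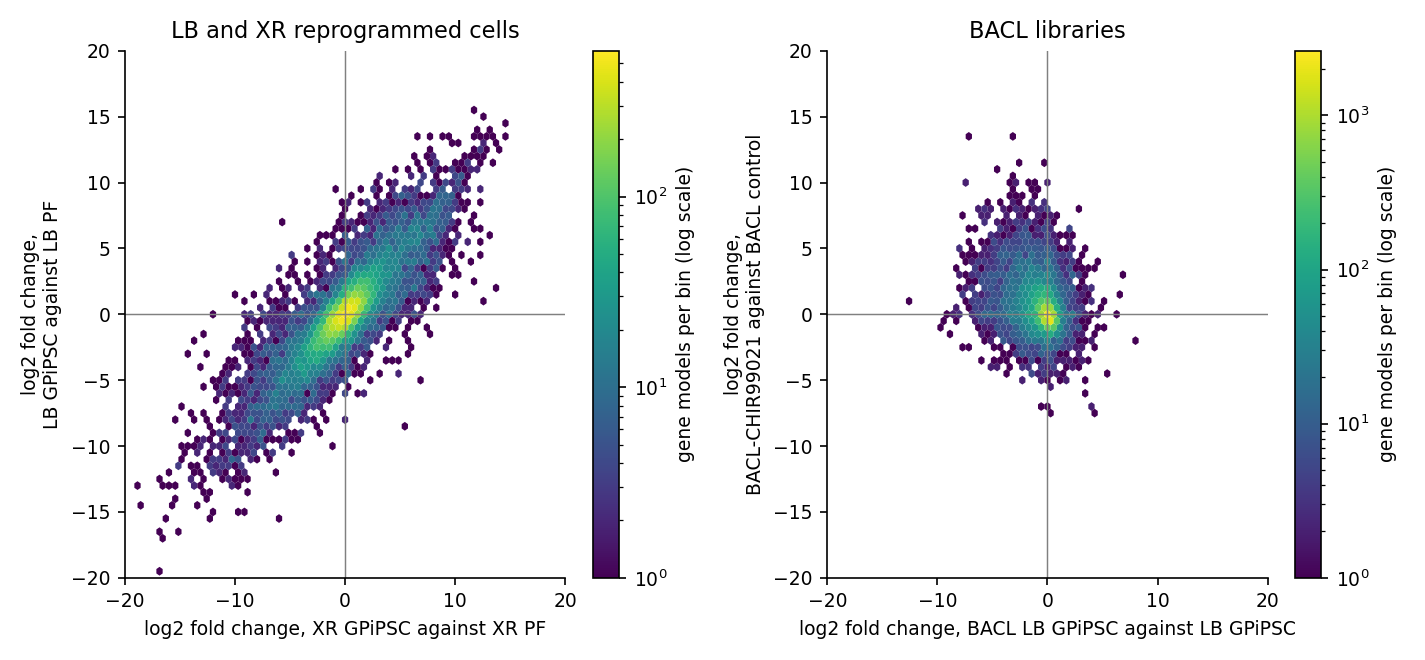
Log2 fold changes of the 17225 tested models in pairs of comparisons that share no library, shaded by the number of models per bin on a log scale. LB against XR changes (left) correlate at 0.85, and BACL-CHIR99021 against BACL LB GPiPSC changes (right) at -0.32.

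Whether the LB and XR changes differed was tested directly. In this test 1489 models passed, 957 with a higher log2 fold change in LB and 532 with a lower one. Among them, 114 were called in opposite directions in LB and XR, 568 in the same direction, 406 in LB alone and 401 in XR alone. Of the 957, 703 were also lower in LB PF than in XR PF and 131 higher in LB GPiPSC than in XR GPiPSC, and of the 532, 379 were higher in LB PF and 62 lower in LB GPiPSC. Independent lists would share 90.7, 11.5, 26.8 and 5.84, but part of the excess can come from the libraries these tests share. At an unadjusted p under 0.05 the overlaps were 1909, 708, 1210 and 512, against at most 224, 160, 198 and 137 in 10 simulations with these 4 groups unchanged. Fewer models differed in the simulations, with a mean of 0.2 calls of the difference at an adjusted p under 0.05 against 1489. They therefore do not show how much of the overlap comes from the shared libraries. The 4 models at the ends of the list had counts in some libraries and 0 in others. Among them, evm.model.HIC_ASM_19.315 and evm.model.HIC_ASM_19.327 have the same coding length. The former had 434, 384 and 0 counts in LB GPiPSC replicates 1, 2 and 3, and the latter 428, 383 and 765. Reads may be divided between these 2 models, so 0 counts in either do not show that it was off. Their opposite changes are therefore not shown to be separate. In XR, evm.model.HIC_ASM_4.1759 and evm.model.HIC_ASM_19.315 stood at 41.8 ± 15.5 and 82.7 ± 41.2 CPM in PF and at 0 in both GPiPSC libraries. In LB PF they stood at 18.8 ± 16.9 and 50.4 ± 30.1 CPM, and in LB GPiPSC at 26.0 and 28.1 CPM in replicate 1, 33.2 and 23.9 in replicate 2 and 0 in replicate 3. The reverse held for evm.model.HIC_ASM_19.328 and evm.model.HIC_ASM_19.327, which were at 0 in both XR PF libraries and at 126 ± 5.73 and 48.5 ± 3.13 CPM in XR GPiPSC, while LB PF replicate 1 had 55.0 and 32.6 CPM, LB PF replicate 2 had 0 of either and LB GPiPSC had 91.4 ± 32.4 and 33.6 ± 13.6 CPM (SD, n = 3). Their edgeR adjusted p-values were 0.00903, 0.0117, 0.0188 and 0.0144. The first pair lost the call without XR GPiPSC replicate 1 (0.0569 and 0.0710) or 2 (0.0510 and 0.0615), and the second pair without LB PF replicate 1 (1.000 for both) or XR PF replicate 2 (0.0885 and 0.0593). The number of calls was 3678 without LB PF replicate 1, 990 without LB GPiPSC replicate 1, 3353 and 707 without XR PF replicates 1 and 2, 503 and 644 without XR GPiPSC replicates 1 and 2, and 95, 47 of them higher in LB and 48 lower, when only these 9 libraries entered the fit.

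LB GPiPSC replicate 3 stood apart from its group. Its log2 CPM correlated at 0.981 with the XR GPiPSC libraries and at 0.962 with LB GPiPSC replicates 1 and 2. Along scaffold HIC_ASM_1, 234 expressed models numbered 1181 to 2178 were higher as a block in XR GPiPSC than in LB GPiPSC replicates 1 and 2, by a median log2 ratio of 0.61 and 0.58 in the 2 XR libraries. In LB GPiPSC replicate 3 the same block was higher by 0.55, or 1.46-fold, with 96.2% of its models above 0, while the 212 models before it on the scaffold had a median of -0.00. Without replicate 3, the test of the LB and XR difference called 1886 models, and with an estimated correlation none of the 24 list tests changed its side of the threshold.

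**Figure D3:**
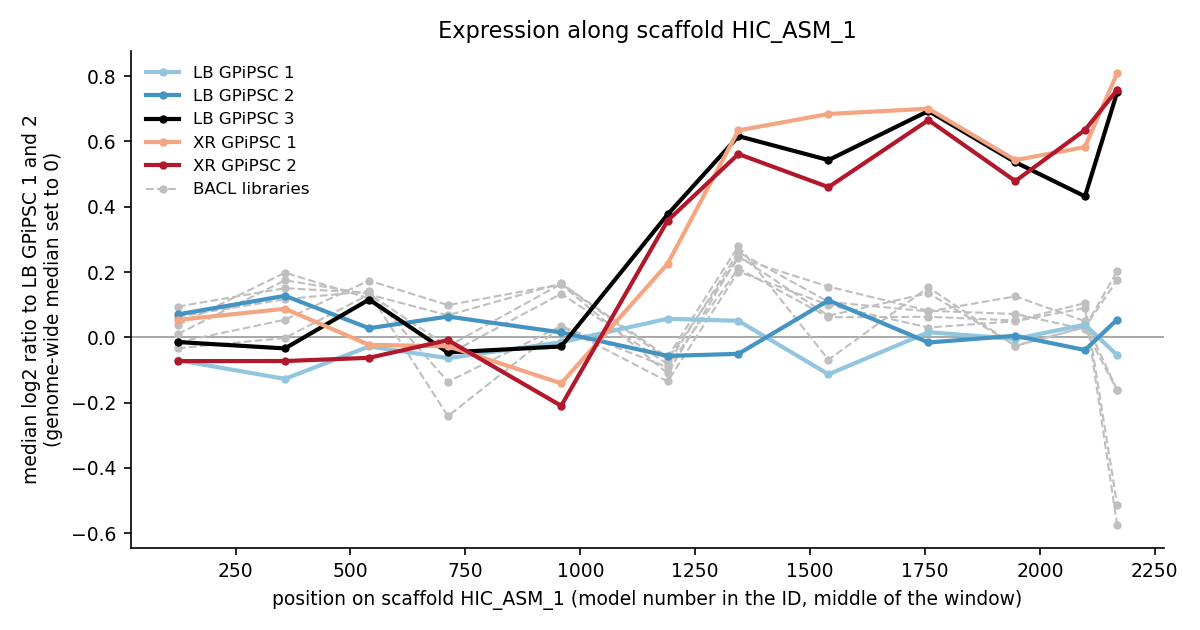
Median log2 ratio of each GPiPSC and BACL library to LB GPiPSC replicates 1 and 2 (each of these 2 against the other) in windows of up to 40 expressed models along scaffold HIC_ASM_1, with the number in the identifier taken as the order. LB GPiPSC replicate 3 and both XR GPiPSC libraries are raised from model 1181 on, with block medians of 0.55, 0.61 and 0.58.

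Gene models that separate GPiPSC from PF give a scale for the other samples. Those over 2-fold higher in both LB and XR GPiPSC (GPiPSC-high, 2847 models) and those over 2-fold lower in both (PF-high, 3128 models) were placed between the mean of the 4 PF libraries (0%) and that of the 5 GPiPSC libraries (100%), which the choice of models sets. At stage I day 8 the GPiPSC-high models stood at 10.6 ± 3.60% and the PF-high models at 1.05 ± 1.07% of the way (SD, n = 2). At stage I day 24 they stood at 61.3 ± 5.50% and 24.2 ± 2.71%, and at stage II day 8 at 66.4 ± 2.15% and 53.2 ± 0.0441%. These positions depend on the scale. On log2(TPM + 1) they were -6.66 ± 5.04% and 20.4 ± 6.60% at stage I day 8, 35.0 ± 22.3% and 44.7 ± 23.98% at day 24 and 34.6 ± 5.61% and 83.1 ± 3.24% at stage II day 8. On log2(TPM + 0.1) the last 2 were 41.7 ± 5.29% and 78.1 ± 3.83%. RLE, which like TMM corrects for library composition where TPM does not, gave 64.9 ± 1.83% and 54.4 ± 0.242% at stage II day 8. One pattern of deviation from the group means held 32.1% of the spread between all replicates. It was strongest at stage I day 24 (57.8 and -57.8 on an arbitrary scale), in XR PF (-56.3 and 56.3) and at stage I day 8 (29.0 and -29.0), and weaker in LB GPiPSC (14.8, 5.75 and -20.5), at stage II day 8 (-17.7 and 17.7) and in A83-01 (-14.0 and 14.0).

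**Figure D4:**
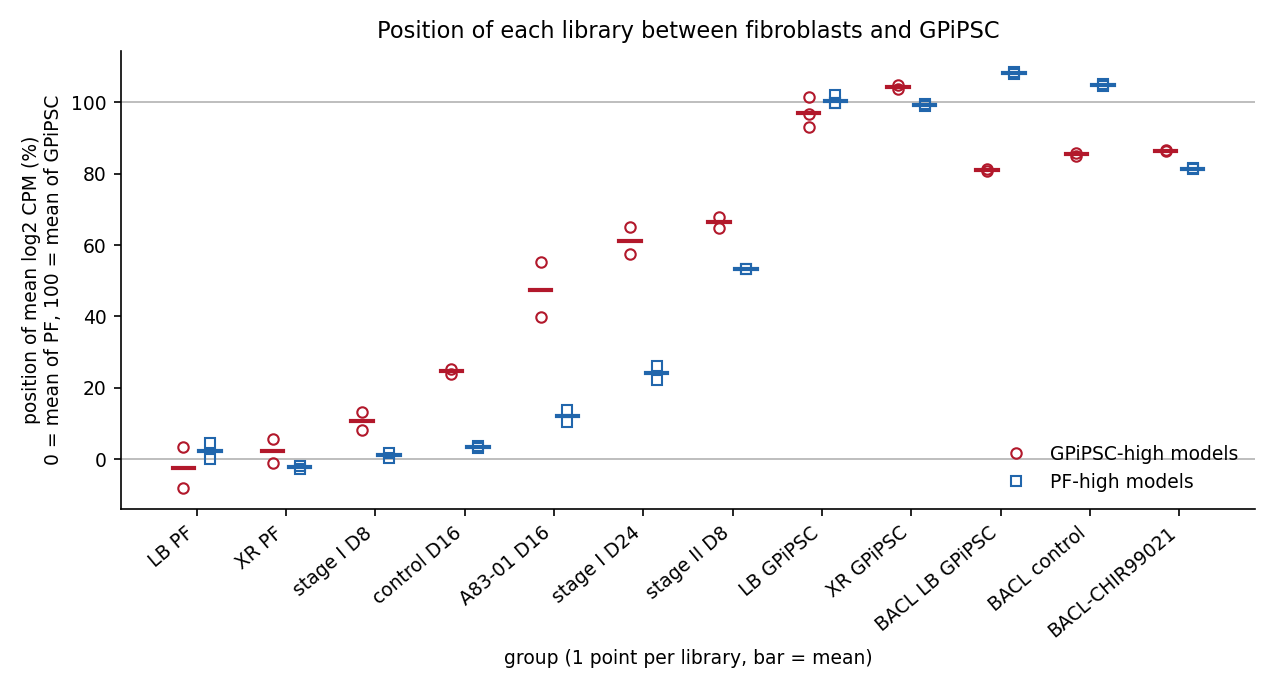
Position of each library (points) and group mean (bars) for the mean TMM-scaled log2 CPM over the GPiPSC-high models (circles) and the PF-high models (squares), with 0% at the mean of the PF libraries and 100% at that of the GPiPSC libraries. At stage I day 24 the GPiPSC-high models are at 61.3% and the PF-high models at 24.2%, against 35.0% and 44.7% on log2(TPM + 1), which is not drawn.

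Stage I day 8 was compared with the mean of LB and XR PF, and 4471 models were higher and 4418 lower. The model evm.model.HIC_ASM_5.1629 stood at 2086 ± 499 CPM, against 0.0820 ± 0.116 in LB PF and 2.96 ± 1.33 in XR PF (SD, n = 2 each), and evm.model.HIC_ASM_7.35 at 491 ± 38.5 CPM, against 0.387 ± 0.0328 and 0.561 ± 0.00611. The models evm.model.HIC_ASM_10.40 and evm.model.HIC_ASM_12.1639 were at 0.562 ± 0.0861 and 0.853 ± 0.0328 CPM, against 267 ± 46.9 and 113 ± 36.9 in LB PF and 15.0 ± 8.49 and 19.03 ± 8.52 in XR PF, with log2 fold changes of -6.78 ± 0.63 and -5.75 ± 0.72 (SE). For these 4 models edgeR gave adjusted p-values of 8.76e-11, 1.09e-14, 1.38e-06 and 4.81e-06. Models that separate LB GPiPSC from LB PF moved in both directions against XR PF, the libraries they were not drawn from. Of those over 2-fold higher in LB GPiPSC, 807 rose and 752 fell, with a median of 0.00 against -0.06 in the other models, or -0.04 against -0.38 on log2(TPM + 1) (adjusted p = 0.731 with an estimated correlation), and of those over 2-fold lower, 762 rose and 977 fell (adjusted p = 0.636). Without stage I day 8 replicate 1 the count was 4736, with the shared deviation as a covariate 4489, and with only the libraries of these 3 groups in the fit 4793. Of the calls made by limma-trend on log2(TPM + 1), 28.8% were higher against 50.3%, and the median over all models was -0.29 against 0.00.

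Between day 8 and day 24 of stage I, GPiPSC-high models rose and PF-high models fell. Of the 2847 GPiPSC-high models, 1500 rose and 95 fell, with a median log2 fold change of 1.65 against -0.00 in the other models (adjusted p = 0.00202 with an estimated correlation). These medians were 0.66 against 0.06 on log2(TPM + 1) and 1.29 against 0.07 on log2(TPM + 0.1). Of the 3128 PF-high models, 180 rose and 1143 fell, with a median of -0.71 against 0.31 (adjusted p = 7.98e-06). In all, 3211 models were higher and 2388 lower at day 24, and the median over all models was 0.15. The model evm.model.HIC_ASM_10.1755 rose from 0.646 ± 0.326 to 604 ± 433 CPM (SD, n = 2 each; log2 fold change 9.89 ± 0.77 SE, 10.48 without stage I day 8 replicate 1 and 8.86 without day 24 replicate 1), and evm.model.HIC_ASM_10.104.1 from 0.583 ± 0.238 to 124 ± 5.15 CPM (7.73 ± 0.81 SE). The models evm.model.HIC_ASM_8.405 and evm.model.HIC_ASM_4.615 fell from 311 ± 152 to 0.694 ± 0.236 CPM (-8.75 ± 0.63 SE, and -8.13 without day 8 replicate 2) and from 3197 ± 239 to 12.8 ± 5.67 CPM (-7.98 ± 0.88 SE). The edgeR adjusted p-values of the 4 were 5.56e-08, 1.69e-06, 6.69e-08 and 1.49e-06. Only the libraries of these 2 groups in the fit gave 2484 calls. Without stage I day 24 replicate 2, 2592 models were higher and 2507 lower, and the median over all models was -0.06.

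From stage I day 24 to stage II day 8, PF-high models fell further. Of these, 1225 fell and 136 rose, with a median log2 fold change of -0.90 against 0.00 in the other models (adjusted p = 4.77e-05 with an estimated correlation). Of the GPiPSC-high models, 572 rose and 297 fell, with a median of 0.18 against -0.22, but this list did not pass with an estimated correlation (adjusted p = 0.231), and on log2(TPM + 1) the medians were -0.04 against -0.27. In all, 2183 models were higher and 3279 lower, and the median over all models was -0.15. The model evm.model.HIC_ASM_4.615, lower at day 24 than at day 8, rose from 12.8 ± 5.67 to 1781 ± 299 CPM (SD, n = 2 each; log2 fold change 7.13 ± 0.85 SE), both comparisons sharing the day 24 libraries, and evm.model.HIC_ASM_12.1074 rose from 2.01 ± 0.606 to 244 ± 19.2 CPM (6.89 ± 0.42 SE). The models evm.model.HIC_ASM_0.188 and evm.model.HIC_ASM_13.1359 fell from 1542 ± 601 to 3.48 ± 0.293 CPM (-8.79 ± 0.76 SE) and from 144 ± 53.3 to 0.672 ± 0.0306 CPM (-7.72 ± 0.79 SE). The edgeR adjusted p-values of the 4 were 1.02e-05, 9.85e-09, 2.77e-07 and 9.31e-06. Without stage I day 24 replicate 2 the count was 2744 and the median over all models 0.00, without stage II day 8 replicate 2 it was 2210, and with only these 2 groups in the fit 1886. By limma-trend, 33.3% of calls on log2(TPM + 1) and 28.5% on log2(TPM + 0.1) were higher against 39.97%, and the median over all models was -0.22 and -0.35.

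The step from stage II day 8 to established GPiPSC held the most calls of the 10 comparisons in the test with all libraries. Against the mean of LB and XR GPiPSC, 5342 models were higher and 6258 lower in the GPiPSC. The models evm.model.HIC_ASM_13.734 and evm.model.HIC_ASM_15.38 were at 4.49 ± 2.06 and 0.554 ± 0.477 CPM at stage II day 8 (SD, n = 2), at 426 ± 59.9 and 44.7 ± 18.97 in LB GPiPSC (SD, n = 3) and at 700 ± 48.3 and 79.4 ± 4.32 in XR GPiPSC (SD, n = 2), with a log2 fold change of 6.92 ± 0.31 (SE) for the first. The models evm.model.HIC_ASM_13.784 and evm.model.HIC_ASM_1.1029 were at 17851 ± 3147 and 409 ± 74.2 CPM at stage II day 8, at 0.493 ± 0.420 and 0.634 ± 0.340 in LB GPiPSC and at 0.0936 ± 0.0413 and 0 in XR GPiPSC. The edgeR adjusted p-values of the 4 were 3.12e-12, 5.31e-07, 5.74e-13 and 1.59e-12. Lists drawn from the LB libraries were tested in XR GPiPSC. Of the 4238 models over 2-fold lower in LB GPiPSC than in LB PF, 1906 fell and 757 rose, with a median of -0.87 against 0.15 in the other models (adjusted p = 0.000137 with an estimated correlation), whereas on the TPM scale the list's median was 0.05 against 0.77. Of the 4091 over 2-fold higher, 1611 rose and 958 fell (adjusted p = 0.161). In limma-trend on log2(TPM + 1) 76.5% of calls were higher against 46.1%, and the median over all models was 0.55 against -0.08. RLE gave 48.1%, but like TMM it corrects for library composition, which TPM does not, so it does not bear on that part of scaling. Mean TMM factors were 1.32 in LB GPiPSC and 1.25 in XR GPiPSC against 0.706 at stage II day 8, which goes in the direction of the TPM shift. With the shared deviation as a covariate 2454 models were called, 569 higher and 1885 lower.

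A83-01, an inhibitor of the TGF-beta and activin type I receptors, was compared with its control at day 16. Of the GPiPSC-high models, 505 rose and 30 fell with A83-01, with a median log2 fold change of 0.65 against -0.01 in the other models (adjusted p = 0.00594 with an estimated correlation). These medians were 0.30 against -0.03 on log2(TPM + 1) and 0.51 against -0.04 on log2(TPM + 0.1). Of the PF-high models, 164 fell and 29 rose, with a median of -0.23 against 0.10 (adjusted p = 9.71e-05). On the scale between PF and GPiPSC, the treated libraries stood at 47.5 ± 10.9% for the GPiPSC-high models against 24.6 ± 0.902% in the control, and at 12.1 ± 2.33% against 3.42 ± 0.283% for the PF-high models (SD, n = 2 each). With log2(TPM + 1) these positions were 37.7 ± 16.3% against 18.4 ± 0.749% and 9.30 ± 5.12% against -2.74 ± 0.642%. In all, 721 models were higher and 351 lower. Of the 683 models over 2-fold higher with A83-01, 573 also rose and 16 fell between day 8 and day 24 of stage I (median 3.52, adjusted p = 0.000137 with an estimated correlation), and of the 311 over 2-fold lower, 223 fell and 8 rose (median -1.97, adjusted p = 6.7e-06). The medians of these lists were 1.74 and -1.33 on log2(TPM + 1) and 2.95 and -1.81 on log2(TPM + 0.1). The same lists moved likewise in LB GPiPSC against LB PF, where 555 of the former rose and 43 fell (adjusted p = 0.00117) and 164 of the latter fell and 45 rose (adjusted p = 0.00329). In XR GPiPSC against XR PF, 521 of the former rose and 43 fell (adjusted p = 0.00526), and 201 of the latter fell and 32 rose (adjusted p = 0.000225).

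Single models responded unevenly between the A83-01 replicates. The models with the largest rise, evm.model.HIC_ASM_11.478 and evm.model.HIC_ASM_2.519, stood at 1.45 ± 0.0855 and 7.61 ± 1.95 CPM in the control and at 3.43 and 18.5 CPM in A83-01 replicate 1 against 867 and 1439 in replicate 2 (edgeR adjusted p = 0.00613 and 0.00340). Neither passed without A83-01 replicate 2 (adjusted p = 0.848 and 0.530), without control replicate 1 (0.107 and 0.0600) or without control replicate 2 (0.112 and 0.0844). The models evm.model.HIC_ASM_2.1106 and evm.model.ORI_1550.3 fell from 51.8 ± 1.22 to 0.888 ± 0.842 CPM and from 21.3 ± 1.63 to 0.576 ± 0.115 CPM (SD, n = 2 each), with log2 fold changes of -5.88 ± 0.59 (-5.16 and -7.43 without A83-01 replicates 1 and 2) and -5.18 ± 0.72 (SE) and edgeR adjusted p-values of 0.000135 and 0.000189. The number of calls was 385 and 308 without control replicates 1 and 2, 375 without A83-01 replicate 1 and 2173, of which 1054 were higher and 1119 lower, with only these 4 libraries in the fit. Of the calls 67.3% were higher, against 80.7% without A83-01 replicate 2 (642 and 154), and 57.2% and 68.2% by limma-trend on log2(TPM + 1) and log2(TPM + 0.1).

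BACL LB GPiPSC were compared with LB GPiPSC, and most of the models called were lower. There were 1327 lower models, 505 of them over 8-fold, and 309 higher ones. The models evm.model.HIC_ASM_0.798 and evm.model.HIC_ASM_2.924 fell from 95.8 ± 67.6 to 1.74 ± 0.0903 CPM and from 49.4 ± 41.2 to 0.938 ± 0.00406 CPM (SD, n = 3 and 2), with log2 fold changes of -5.77 ± 0.62 (-5.09 without LB GPiPSC replicate 2) and -5.70 ± 0.82 (-4.96 without LB GPiPSC replicate 3), with SE. The models evm.model.HIC_ASM_2.1266 and evm.model.HIC_ASM_3.1518 rose from 6.57 ± 3.02 to 119 ± 3.78 CPM and from 2.11 ± 0.949 to 26.7 ± 1.42 CPM, with log2 fold changes of 4.18 ± 0.51 and 3.65 ± 0.36 (SE). The edgeR adjusted p-values of the 4 were 9.74e-06, 0.000188, 6.87e-05 and 5.06e-06. Of the models over 2-fold higher in XR GPiPSC than in XR PF, 523 fell and 57 rose, with a median of -0.25 against -0.01 in the other models (adjusted p = 0.248 with an estimated correlation), and of those over 2-fold lower, 454 fell and 108 rose, with a median of -0.14 against -0.04 (adjusted p = 0.546) that lay 0.05 above the others on the TPM scale. At 1 CPM or more, 13274 ± 9.90 models were expressed, against 14030 ± 72.1 in LB GPiPSC. The median difference of coding and effective length, a measure of fragment length, was 288 ± 1.41 bases against 309 ± 3.03. The count was 465 and 479 without BACL LB GPiPSC replicates 1 and 2, and 1334 without LB GPiPSC replicate 3, and with only these 5 libraries in the fit 590 models were higher and 970 lower, 943 of the 1636 calls being shared. The median over all models was -0.06, and -0.14 and -0.19 on log2(TPM + 1) and log2(TPM + 0.1).

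BACL-CHIR99021 was compared with BACL control. CHIR99021 inhibits the kinase GSK-3, and the label does not say whether it was added or left out, so directions are given only as BACL-CHIR99021 against control. Of the PF-high models, 817 were higher and 52 lower in BACL-CHIR99021, with a median log2 fold change of 0.62 against -0.06 in the other models (adjusted p = 5.98e-05 with an estimated correlation), and their position was 81.4 ± 0.325% against 105 ± 0.248% in the control (SD, n = 2 each). Of the GPiPSC-high models, 348 were higher and 284 lower, with a median of -0.20 against 0.02 in the other models, or 0.03 against 0.17 on log2(TPM + 1), and a mean of 0.07 (adjusted p = 0.517 with an estimated correlation). In all, 2010 models were higher and 763 lower. The models evm.model.HIC_ASM_7.203 and evm.model.HIC_ASM_8.1083 rose from 1.150 ± 0.133 to 1374 ± 12.9 CPM and from 0.528 ± 0.219 to 214 ± 9.95 CPM (SD, n = 2 each), with log2 fold changes of 10.21 ± 0.59 and 8.64 ± 0.52 (SE). The models evm.model.HIC_ASM_2.1266 and evm.model.HIC_ASM_3.1518, higher in BACL LB GPiPSC, were lower here, at 0.483 ± 0.146 CPM against 58.3 ± 3.98 and 0.877 ± 0.167 against 58.1 ± 3.49, with log2 fold changes of -6.88 ± 0.73 and -6.03 ± 0.48 (SE). The edgeR adjusted p-values of the 4 were 2.97e-09, 3.84e-09, 5.69e-06 and 1.03e-07. The count was 1327 and 1351 without control replicates 1 and 2, 1582 and 1553 without BACL-CHIR99021 replicates 1 and 2, and 10940, of which 5615 were higher and 5325 lower, when only these 4 libraries entered the fit. By limma-trend, 82.2% of calls on log2(TPM + 1) and 85.3% on log2(TPM + 0.1) were higher against 72.5%, and the median over all models was 0.15 and 0.23 against 0.00.

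The changes in BACL LB GPiPSC and in BACL-CHIR99021 were then set against each other, since these comparisons share no library. Of the 1245 models over 2-fold lower in BACL LB GPiPSC than in LB GPiPSC, 509 were higher and 45 lower in BACL-CHIR99021 than in BACL control, with a median log2 fold change of 1.13 (adjusted p = 0.000916 with an estimated correlation). Their median was 0.59 against 0.13 in the other models on log2(TPM + 1), and 1.12 against 0.20 on log2(TPM + 0.1). Of the 194 over 2-fold higher, 19 were higher and 52 lower, with a median of -0.27 (adjusted p = 0.00474), or -0.02 against 0.15 in the other models on log2(TPM + 1). Among all calls, 548 models were lower in the former and higher in the latter, where independent lists would share 155, and 81 were higher in the former and lower in the latter, where 13.7 would be shared. Higher in both were 24 models against 36.1, and lower in both 48 against 58.8. In BACL control the lower and the higher models stood at a median log2 CPM of 0.82 and 2.37, against 3.61 in the models of neither list. In 1000 draws of as many of these others at matched levels in BACL control, the median log2 fold change lay between 0.10 and 0.32 for the former and between -0.17 and 0.24 for the latter.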

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

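All tests of LB GPiPSC replicate 3, and the test of a library batch alone for the BACL libraries, were chosen after the result was seen.

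The difference between the LB and XR changes, GPiPSC against PF, was singled out because the test of the difference itself called models. It called 1489, and 1886 without LB GPiPSC replicate 3, but 391 with glmTreat against 2-fold and 95 with only the libraries compared in the fit.

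LB GPiPSC replicate 3 lay nearer the XR GPiPSC libraries than its own group, and depth is argued against, since with every library thinned to the smallest total its mean correlation with XR GPiPSC still exceeded that with LB GPiPSC replicates 1 and 2 by 0.0175 (0.0192 before). An LB culture in another state with the dosage of the LB line is argued against by the block on HIC_ASM_1, raised by 0.55, although the margin over its largest run of as many models on another scaffold was small (0.478, on HIC_ASM_15, where the XR libraries were also raised, by 0.33 and 0.44). An LB culture that gained this block on its own was first tested on 13 models off that scaffold, of which replicate 3 was nearer the XR level in 11 and LB GPiPSC replicates 1 and 2 in 4 and 7, which left it undecided. A test chosen after that result argues against a gain of this block alone, since all 3 of the strongest steps along scaffolds, found without replicate 3, were present in it: HIC_ASM_1, HIC_ASM_4 models 10 to 545 (0.59, against 0.70 and 0.57 in XR GPiPSC) and HIC_ASM_0 models 2000 to 2255 (-0.87, against -1.18 and -1.08), the last of which is not particular to XR GPiPSC, being also present in BACL control and BACL-CHIR99021 (-0.89 to -1.02). Finding and measuring the steps shared LB GPiPSC replicates 1 and 2 as the reference, so a shift peculiar to these would appear in both. BACL LB GPiPSC lay near that reference on HIC_ASM_1 (0.07 and 0.08), HIC_ASM_4 (0.11 in both) and HIC_ASM_0 (-0.06 and -0.05). A wrong label, the library holding cells of the XR GPiPSC line, may account for the pattern as a hypothesis found and tested on the same libraries, and neither separate changes on several scaffolds nor an origin shared by the cultures, which the labels do not describe, was tested.

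Several groups shared a deviation from their group means, strongest in XR PF and at stage I day 24, seen as a correlation across models of 0.714 between XR PF replicate 2 minus 1 and stage I day 24 replicate 1 minus 2. It was 0.701 after a smooth trend on coding length was removed, 0.715 without the 44 most abundant models and 0.696 with every library thinned to the smallest total, which argues against each of these as the whole cause. The replicate with the higher score had the lower TMM factor in XR PF (0.723 against 0.870) and at stage I day 24 (0.714 against 1.05). The same held at stage I day 8 (0.622 against 0.695) and stage II day 8 (0.664 against 0.747). It did not hold in LB GPiPSC (1.33, 1.30 and 1.32 in replicates 1 to 3). Whether library composition lies behind the deviation was not tested. The scores on this deviation also differ between groups, so calls that end with it as a covariate are not shown to be technical. GC content was not tested, as no sequences were used here, and no biological explanation was tested.

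Many models differed between BACL LB GPiPSC and LB GPiPSC, and the state of LB GPiPSC replicate 3 is argued against as the whole cause by the 1334 calls made without it, which share 1172 of the 1636 in the same direction. A library batch cannot be told apart from whatever the BACL label stands for, since the labels give no batch. Models over 2-fold lower in BACL LB GPiPSC rose by 1.13 above the other models in BACL-CHIR99021 against BACL control. This does not bear on a batch, as that comparison has a condition of its own. Effective lengths are argued against as the whole cause, since 1498 models were called with length offsets, and 1437 of the 1636 calls were kept in the same direction. A part played by them cannot be told apart, since fold changes correlated at 0.162 with the log2 ratio of effective lengths. A response to whatever the BACL label stands for, which the labels do not explain, may account for the rest. It was not tested apart from other differences between these libraries.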

How the results depend on the processing

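The covariate for the shared deviation, the drawn lists, their medians and positions on the TPM scale and the list tests without LB GPiPSC replicate 3 were chosen after the data were examined. Of 156 alternative counts over the 10 comparisons, 115 stayed within 1.5 times the main count. RLE, no filter, the replicate block, length offsets, both TPM scales and LB or XR alone as reference stayed within 1.5 times in every comparison. In the order LB, XR, their difference, stage I day 8, day 24, stage II day 8, GPiPSC against stage II, A83-01, BACL LB and BACL-CHIR99021, glmTreat against 2-fold called 5962, 5868, 391, 3545, 2445, 1475, 6830, 300, 542 and 1134, fewer by construction. Fits of only the libraries compared called 95 (difference), 4793 (stage I day 8), 2484 (day 24), 1886 (stage II day 8), 2173 (A83-01) and 10940 (BACL-CHIR99021), and DESeq2 2423 (difference). The covariate gave 2843 (difference), 4489 (stage I day 8), 2454 (GPiPSC against stage II), 2059 (A83-01), 3131 (BACL LB) and 4852 (BACL-CHIR99021). Leaving out single libraries gave 503 to 3678 (difference), 4736 to 9703 (stage I day 8), 2210 to 6902 (stage II day 8), 308 to 796 (A83-01), 465 to 1645 (BACL LB) and 1327 to 1582 (BACL-CHIR99021). For DESeq2, the covariate and the fits of the libraries compared, the cause was not tested. The main fit pools 1 spread per model over all groups. With their own spread, BACL control and BACL-CHIR99021 (replicate chi-square per degree of freedom 1.61 and 1.54) went from 2773 to 10940 calls. The difference, which includes LB PF (118) and XR PF (119), went from 1489 to 95. Counts of calls in different comparisons are therefore not on the same footing. The replicate block, tried because groups share numbers, called 9142, 9507, 1617, 8736, 5507, 5298, 11303, 1038, 1205 and 2737 in the order above. Replicate deviations of 15 pairs of groups correlated between -0.545 and 0.558, and 3 exceeded 0.1, so the numbers were not taken to pair libraries. Named models were tried only with RLE, DESeq2, the replicate block, length offsets and single libraries left out. The TPM scales, no filter, glmTreat, the covariate and fits of only the libraries compared were not tried for them. Of 368 such alternatives for 40 named models, 354 kept the call, 14 lost it and none changed direction. These models were picked for their large changes in the main fit, which favours keeping the call. Of 144 alternatives for the 24 list tests, 133 kept the side of the threshold they had with the preset correlation, 10 lost the call and 1 gained it. With 2 libraries in most groups, the simulated 2-fold changes were mostly not detected.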

Other observations

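The overlaps, models and blocks in this part were chosen after the data were examined. The models that answered A83-01 and those that differed in BACL-CHIR99021 overlapped mostly in opposite directions, in comparisons that share no library. Lower with A83-01 and higher in BACL-CHIR99021 were 134 models, where independent lists would share 41.0, and 76 were higher with A83-01 and lower in BACL-CHIR99021, where 31.9 would be shared. Higher in both were 120 models against 84.1, and lower in both 10 against 15.5. Across all models the fold changes correlated at -0.06 (Pearson) and -0.17 (Spearman).

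Some models were on in some libraries and at or near 0 counts in others, and these were picked after their values were seen. The model evm.model.HIC_ASM_19.315 had 0 counts in LB GPiPSC replicate 3, both XR GPiPSC and both BACL control libraries, 2 and 0 counts in BACL-CHIR99021, and 355 to 2040 counts in each of the other 18 libraries. Of the same coding length, evm.model.HIC_ASM_19.327 had 765 counts in LB GPiPSC replicate 3, 719 and 826 in XR GPiPSC and 906 and 875 in BACL control, but 0 in XR PF. Reads may be divided between these 2 models, so 0 counts in the first do not show that it was off. On the same scaffold, evm.model.HIC_ASM_19.328 was at 66.9 and 79.0 CPM in LB GPiPSC replicates 1 and 2 and 59.6 and 62.1 in BACL LB GPiPSC, but at 128 in LB GPiPSC replicate 3, 122 and 130 in XR GPiPSC, 101 in both BACL control libraries and 110 and 108 in BACL-CHIR99021. It had 0 to 11 counts in the fibroblast, stage and day 16 libraries, except 671 in LB PF replicate 1. The model evm.model.HIC_ASM_1.1494 had 0 counts in all LB PF and BACL LB GPiPSC libraries and in LB GPiPSC replicates 1 and 2, and 136 counts in LB GPiPSC replicate 3. It had 40 to 242 counts in each of the remaining libraries, none of which is labelled LB. Being a single model picked after its values were seen, it was not used to weigh the label of replicate 3.

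The block on scaffold HIC_ASM_0 (models 2000 to 2255, 40 of them expressed) was lower not only in XR GPiPSC but also in BACL control, by a log2 ratio of -1.02 and -0.98 to LB GPiPSC replicates 1 and 2, and in BACL-CHIR99021, by -0.89 and -0.90. In BACL LB GPiPSC it stood at -0.06 and -0.05. The blocks on HIC_ASM_1 and HIC_ASM_4 were near the LB GPiPSC level in the BACL libraries, at 0.02 to 0.08 and 0.11 to 0.20.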
